A study of Mus musculus with 22 samples.

How the data were processed

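RNA was measured in 22 tumours that grew in the mouse pancreas after orthotopic implantation of PDA.7940B cells, a polyclonal pancreatic ductal adenocarcinoma line. Per the labels' protocols, RNA was extracted with a kit for formalin-fixed, paraffin-embedded tissue from serial sections 5 µm thick, and libraries were made from 100 ng of RNA with a QuantSeq forward kit, which sequences from the 3' ends of polyadenylated transcripts. A value therefore reads the 3' end of a transcript and not its length or isoform. Per the submitters' processing notes, reads were aligned with STAR to mm10 and normalized with DESeq2, with no versions given; the counting program, the gene annotation and the use of strand are not given in the sources used here. Genes that overlap or lie antisense to each other therefore cannot be told apart with certainty, nor can near-identical copies, among them the trypsinogens and elastases, Ly6c2 and Ly6i, Gzmf and Gzmg, and members of the Gbp, Ifit and H2 families.

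The values are normalized counts, a signal in which the authors divided each tumour's read counts by a size factor, in 1 deposited table of 17966 genes by 22 tumours. Within each tumour the values were whole multiples of 1 smallest step: 100% of the 395252 values were whole within 0.001 reads, so read counts were recovered by dividing by that step. For 2 tumours, beta-glucan 1 and 5, the step was within 1% of 1. Recovered depth was 6.33 to 21.2 M reads per tumour. Of the 17966 gene symbols 17699 matched GENCODE M21, the annotation of GRCm38 (mm10) used for coordinates; 23 names had been turned into dates and 2 names occurred more than once. Columns without a sample numbered 0. No pair of tumours within a group agreed within sampling noise: over 50 pairs the lowest chi-square per degree of freedom was 13.4.

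Groups came from the labels: untreated (n = 5), beta-glucan at 1.2 mg (n = 6), anti-CD40 at 0.1 mg (n = 6) and both (n = 5; doses not stated for this group). The labels give each sample a replicate number and do not say whether each tumour came from a separate mouse, so p-values measure the spread between these samples.

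The following choices were made before the data were examined: the groups, the contrasts, the tests, the thresholds, 44 gene lists of cell types and pathways, the rule for the genes named and the first set of alternatives. Genes with a value of at least 10 in at least 5 tumours were tested (14278). Limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) with the means of all 4 groups and trended, robust variance moderation, two-sided. The Benjamini-Hochberg adjustment was applied within each contrast, with a threshold of 0.05. Log2 fold changes are differences of group means on the log2(value + 1) scale, and a fold is 2 to that power and not the ratio of mean counts; for genes with few reads in a group both depend on the pseudocount; the ± after a log2 fold change is its standard error, and the ± after a level is the SD over tumours. The contrasts were each treatment against untreated, the combination against each single treatment, and the interaction, which is the combination minus beta-glucan minus anti-CD40 plus untreated. Where a group held no reads of a gene, the other group's mean count was divided by a floor of 3 reads over the group without reads. That floor is a normalized count of 0.580. Such a ratio of means is given as a lower bound that covers counting error only. It can exceed the fold on the log2(value + 1) scale and is not to be set beside the other folds.

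Lists with at least 4 tested members (41 of the 44) were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. Camera compares a list with the other genes, and its preset correlation is low for markers that rise together with 1 cell type. Camera with an estimated correlation and fry were alternatives. The mean log2 level of each list per tumour was also compared between the 2 groups of a contrast by an exact two-sided permutation test, adjusted over the 41 lists; this test was added after the data were seen. Its smallest possible p is 0.00216 for 6 tumours against 5 and 0.00794 for 5 against 5. A member is counted as higher or lower by its limma call, and a second count is adjusted over the list alone.

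Named genes are the 8 largest rises and falls among called genes with a mean of at least 30 in the higher group, without predicted genes; members with the smallest p, up to 4, of each list that passed; and Clec7a, Cd40, Cd274, Ifng, Tnf, Ccr2, Cd3e, Cd8a, Krt19 and Col1a1 in the contrasts against untreated and in the interaction. Of the list members, the text takes those with the smallest p; some genes that the rule selects are left out of the text and of the counts of named genes. A few list members are named without values because they went against their list or make up a small count; these were chosen after their values were seen.

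The steps were tested on simulated data with 50 genes at each fold, drawn from the means and depths of these libraries over the 14278 genes. For the combination against untreated, limma recovered 60% of genes raised 4-fold, 58% of genes lowered to 0.25 of their level, 22% of genes raised 2-fold and 16% of genes lowered to 0.5, with 1 call among 14058 unchanged genes. Counts of 2-fold changes are thus far from complete at this depth and spread. Camera gave p under 0.05 for 6 of 6 changed and 1 of 6 unchanged lists. The simulated genes were drawn independently of each other, and list members at random. The figures for unchanged genes and lists therefore do not show how often calls arise by chance where genes vary together between tumours.

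Alternatives were a pseudocount of 0.5 or 8, no filter or a mean of at least 50, values rescaled to equal totals, quantile normalization, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, sample weights, a fit of only the groups compared, the replicate number as a block, and each tumour left out in turn. After the data were seen, the acinar level as a covariate and the omission of tumours with over 30% acinar reads were added, and list levels were tested again with equal totals, with quantile normalization (exact test) and with the acinar level in a linear model (t test over 22 tumours). Correlations across tumours were computed on deviations from group means, with 100000 permutations within groups. Groups of the same sizes were also drawn 99 times from the compared tumours and refitted, which with the real grouping makes 100. For the interaction, residuals from an additive fit were rearranged between tumours instead. Counts of groupings or arrangements as large include the real one. Unaligned reads and raw data were not analysed here.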

Results

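The data are 3' mRNA sequencing profiles of 22 mouse pancreatic tumours. The tumours formed from PDA.7940B cells implanted in the pancreas, and the treated ones were taken 10 days after treatment. Untreated tumours (n = 5) were compared with tumours given beta-glucan (n = 6), anti-CD40 (n = 6) or both (n = 5). Beta-glucan is a glucose polymer of fungal cell walls that binds the receptor Dectin-1, and CD40 is a receptor of antigen-presenting cells. The design asks what each agent does to the tumour and whether their joint effect differs from the sum of the single effects. Depth was 7.38 to 9.34 M reads in untreated tumours, 7.13 to 8.74 M with beta-glucan, 6.33 to 21.2 M with anti-CD40 and 12.2 to 18.8 M with the combination. The first principal component of the log2 values held 29.9% of the variance and the second 14.6%. Rn45s, a ribosomal RNA precursor, took 1.20 to 4.79% of the reads of a tumour. The mitochondrially encoded list was not tested, since 0 of its 9 genes were found by name.

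Transcripts of normal pancreas varied widely between tumours. The acinar list (Cela2a, an elastase, Prss1, a trypsinogen, and other digestive enzymes) took 4.84% ± 7.18 (SD, n = 5) of reads in untreated tumours and 5.57% ± 6.54 (n = 6) with beta-glucan. It took 26.8% ± 23.6 (n = 6) with anti-CD40 and 22.97% ± 14.6 (n = 5) with the combination. Over 30% of reads were acinar in anti-CD40 tumours 2 (33.0%), 3 (31.6%) and 6 (64.9%) and in combination tumours 4 (35.0%) and 5 (34.7%), and in each group 1 or more tumours had under 1%. The mean level of the 22 acinar genes was higher by 5.11 on the log2 scale with anti-CD40 and by 5.07 with the combination. The exact permutation test gave p = 0.0671 for anti-CD40, with 4 of 6 tumours above every untreated tumour, and p = 0.0873 for the combination, with 4 of 5 above. Camera gave adjusted p = 4.98e-07 and 9.9e-05, and adjusted p = 0.39 and 0.439 with an estimated correlation. 4 of 22 measured members rose (21 adjusted over the list alone) with anti-CD40, and with the combination 6 of 22 (21 adjusted over the list alone) did. For Cela2a the log2 fold change was 6.92 ± 2.14 with anti-CD40 (adjusted p = 0.0301) and 6.68 ± 2.23 with the combination. Prss1 stood at 4.67 and 4.62, and Bhlha15, an acinar transcription factor, at 5.05 and 5.04. The islet list rose with both, with 10 of 14 (12 adjusted over the list alone) called with anti-CD40 and 9 of 14 (13 adjusted over the list alone) with the combination. Exact adjusted p was 0.0266 and 0.0449, and camera adjusted p was 0.29 and 0.351 with an estimated correlation. It did not pass with values rescaled to equal totals (exact adjusted p = 0.0555 and 0.0566) or with the acinar level in a linear model (log2 1.90 ± 1.11 and 1.82 ± 1.15 against 3.96 and 3.86, adjusted p = 0.157 and 0.163). Chga, a protein of endocrine granules, was at log2 5.09 ± 1.12 and the hormone gene Sst at 4.80 ± 1.30 with anti-CD40.

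**Figure D1:**
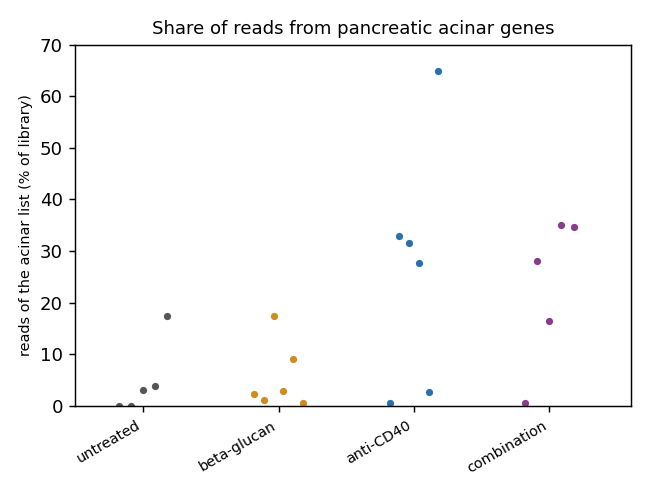
Share of each tumour's reads (percent, vertical axis) that fell in the acinar gene list, by group; each point is 1 tumour. Anti-CD40 tumours span 0.6253 to 64.9% and combination tumours 0.586 to 35.0%, against 0.0383 to 17.3% in untreated tumours.

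Myeloid and stromal transcripts were higher with beta-glucan. The epithelium list was lower, and whether a lower share of epithelium accounts for part of these rises was not tested. Clec4e, the C-type lectin receptor Mincle, rose 21.4-fold (log2 4.42 ± 0.49, adjusted p = 1.08e-05), from a normalized count of 32.5 ± 32.3 (n = 5) to 517 ± 169.8 (n = 6). Dcstamp, a membrane protein of cell fusion in osteoclasts and giant cells, rose 21-fold (log2 4.39 ± 0.36, adjusted p = 9.23e-08), from 10.9 ± 3.26 to 245 ± 47.4. The formyl peptide receptors Fpr2 and Fpr1 rose 16.6-fold and 15.9-fold, and Cxcl3, a chemokine that draws neutrophils, 16-fold. The other leading rises were Tbx1 (log2 4.36 ± 0.98), Best1 (4.14 ± 0.56) and Chga (3.92 ± 1.12). Clec7a, which encodes Dectin-1, rose 4.18-fold (log2 2.06 ± 0.30, adjusted p = 9.71e-05). In all, 916 genes changed, 727 higher and 189 lower, among them 700 by at least 2-fold.

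Of the Dectin-1 pathway list, 12 of 16 measured members rose (13 adjusted over the list alone), with Cybb, the NADPH oxidase heavy chain, 4.52-fold higher. 7 of 13 measured members rose (11 adjusted over the list alone) in the neutrophil list, among them S100a8 (5.86-fold) and the decoy receptor Il1r2 (4.22-fold). Ly6g, a neutrophil surface antigen without reads in any untreated tumour, was at least 29.8-fold higher as a ratio of means. The classically activated macrophage list rose with 4 of 13 members called (9 adjusted over the list alone): Il1b (7.69-fold), Cd86 (4.59-fold), Cxcl9 and Tnf (3.07-fold, adjusted p = 0.0245). Macrophage genes rose in 5 of 15 (12 adjusted over the list alone), with Lyz2 4.34-fold and Ctss 2.99-fold higher. Monocyte genes rose in 3 of 10 (7 adjusted over the list alone), with Treml4 at log2 3.37 ± 0.45 and Itgam at 2.17 ± 0.36. Arg1 and Chil3 rose in the list of suppressive macrophage markers (2 of 12, 5 adjusted over the list alone). Matrix protease genes (6 of 15, 9 adjusted over the list alone) included Mmp9 (8.88-fold) and Mmp3 (6.4-fold). Complement genes (6 of 10, 9 adjusted over the list alone) included Serping1 (3.72-fold) and Cfp (2.92-fold). Collagen matrix genes (8 of 23, 12 adjusted over the list alone) included Col3a1 (2.97-fold), Col1a1 (2.48-fold) and Col5a1 (2.1-fold). Of inflammatory fibroblast genes 5 of 14 (8 adjusted over the list alone) rose, led by the acute phase gene Saa3 (10.6-fold). For these lists and the Dectin-1 list the exact permutation test of the list level gave adjusted p from 0.0111 to 0.0277. All 6 tumours lay above every untreated tumour for the Dectin-1, neutrophil, classically activated macrophage, matrix protease, complement, collagen and inflammatory fibroblast lists. Camera gave adjusted p from 2.96e-13 to 0.000271, and adjusted p from 0.0666 to 0.118 with an estimated correlation.

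Interferon-gamma response genes rose in 11 of 23 (15 adjusted over the list alone), with Serpina3g 5.07-fold and Gbp5 2.9-fold higher. Camera gave adjusted p = 1.19e-08, adjusted p = 0.172 with an estimated correlation, and the exact adjusted p was 0.071. Class I presentation genes rose in 6 of 13 (7 adjusted over the list alone) (exact adjusted p = 0.0444, adjusted p = 0.107 with an estimated correlation). Lymphoid tissue genes rose in 4 of 9 (5 adjusted over the list alone). Glycam1 of that list, an adhesion ligand of high endothelial venules with no reads in untreated tumours, was at least 28.5-fold higher (list exact adjusted p = 0.0148, adjusted p = 0.0666 with an estimated correlation). B cell genes rose in 4 of 14 (8 adjusted over the list alone), among them Pou2af1 (4.25-fold) and Cd79b (5.43-fold). The plasma cell genes Irf4, Jchain and Mzb1 rose among 8 tested (3 adjusted over the list alone). Exact adjusted p for these 2 lists was 0.0654 and 0.0418, and camera adjusted p was 0.179 and 0.204 with an estimated correlation. No T cell gene of 18 was called (0 adjusted over the list alone; camera adjusted p = 0.0387, adjusted p = 0.508 with an estimated correlation, exact adjusted p = 0.2). Class II genes had 0 calls of 9 (0 adjusted over the list alone, camera adjusted p = 0.103). Ccl5 was the 1 cytotoxic lymphocyte gene called of 14 (2 adjusted over the list alone, camera adjusted p = 0.0865). Nfkbia, Nfkbie, Traf1 and Icam1 rose among 19 CD40 and NF-kB genes (5 adjusted over the list alone). Fas, Tnfsf10, Casp1 and Tnfrsf1b rose among 18 cell death genes (5 adjusted over the list alone), and Tie1 and Plvap among 16 endothelial genes (5 adjusted over the list alone). Exact adjusted p was 0.0111, 0.0148 and 0.0254, and camera adjusted p was 0.179, 0.315 and 0.293 with an estimated correlation. The acinar and islet lists passed camera, with adjusted p = 0.647 and 0.339 with an estimated correlation and exact adjusted p = 0.392 and 0.0761. Called were 0 of 22 acinar genes (0 adjusted over the list alone) and Chga of 14 islet genes (1 adjusted over the list alone).

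The epithelium list fell with beta-glucan: 2 of 19 genes, Elf3, an epithelial transcription factor (log2 -1.50 ± 0.42), and Cldn7, a tight junction protein (-1.06 ± 0.32), were lower (5 adjusted over the list alone). So did the glycolysis and hypoxia list, with 2 of 20 genes, Bnip3 (-0.82 ± 0.21) and Pfkl (-0.97 ± 0.27), lower (2 adjusted over the list alone). In both lists all 6 tumours lay below every untreated tumour (exact adjusted p = 0.0111 for each), and camera with an estimated correlation gave adjusted p = 0.177 and 0.107. Rpl7 was lower among 20 ribosomal protein genes (1 adjusted over the list alone; camera adjusted p = 0.0094, exact adjusted p = 0.278, adjusted p = 0.218 with an estimated correlation). The largest falls were Cym, the milk-clotting protease chymosin (log2 -3.38 ± 0.9999), Tmem212 (-2.98 ± 0.90), Dmkn (-2.97 ± 0.84), the keratin Krt4 (-2.82 ± 0.83), Ckmt1 (-2.67 ± 0.72), Bcl7a (-2.53 ± 0.76) and the brush border myosin Myo1a (-2.43 ± 0.67). Cd40 (log2 0.69, adjusted p = 0.356), Cd274, which encodes PD-L1 (0.96, 0.234), Ifng (0.17, 0.936), Ccr2 (1.28, 0.0815), Cd3e (1.18, 0.236), Cd8a (0.44, 0.627) and Krt19 (-1.17, 0.21) did not pass. Of all 14278 genes 6.85% had no overlap between the groups (chance share 0.433%), and 20 of the 44 named genes that passed lost their call in at least 1 alternative fit. The count of 916 genes was 600 without untreated tumour 1, 579 without untreated tumour 5, 609 without beta-glucan tumour 3 and 506 without beta-glucan tumour 5. It was 257 with values rescaled to equal totals, of which 93.0% were higher against 79.4% of the 916. With quantile normalization the plasma cell and class I lists no longer passed the exact test (adjusted p = 0.0592 and 0.0607).

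Anti-CD40 raised transcripts of lymphocytes and of antigen presentation. Mzb1, a chaperone of antibody-secreting cells, rose 122-fold (log2 6.93 ± 0.83, adjusted p = 6.37e-06), from a normalized count of 6.16 ± 6.82 (n = 5) to 526 ± 230.2 (n = 6). This fold depends on the pseudocount, as 2 untreated tumours had no reads (log2 5.28 at a pseudocount of 8). Jchain, the joining chain of secreted antibodies, rose 90.7-fold. The B cell gene Pax5 rose 69.7-fold. Ccl5, a chemokine of activated T cells, rose 30.6-fold (log2 4.94 ± 0.45, adjusted p = 2.47e-07) and Ly6c2, an antigen of inflammatory monocytes, 68-fold. Glycam1 was at least 120-fold and the class II gene H2-Eb2 at least 111-fold higher, as neither had reads in untreated tumours. In all, 2650 genes changed, 1571 higher and 1079 lower, among them 1841 by at least 2-fold.

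Of B cell genes 13 of 14 (14 adjusted over the list alone) rose, with Pou2af1 40.2-fold and Cd79b 35.6-fold higher. Of T cell genes 13 of 18 (14 adjusted over the list alone) rose, among them Cd3e (15-fold), Cd2 (16.9-fold) and the kinase Lck (8.2-fold). Of cytotoxic lymphocyte genes 12 of 14 (13 adjusted over the list alone) rose, with Nkg7 10.5-fold, Cd8a 5.71-fold and Ifng 13.2-fold higher. Regulatory and inhibitory receptors rose in 7 of 10 (8 adjusted over the list alone), with Icos 12.1-fold and Tnfrsf18 4.52-fold higher. Plasma cell genes rose in 5 of 8 (6 adjusted over the list alone), with Irf4 26.1-fold higher, while Sdc1, which epithelium also expresses, was lower. Lymphoid tissue genes rose in 6 of 9 (6 adjusted over the list alone), with the B cell chemokine Cxcl13 29.1-fold higher. Class II genes rose in 9 of 9 (9 adjusted over the list alone), among them H2-Aa (5.96-fold) and H2-Ob (20.4-fold). Class I presentation genes rose in 10 of 13 (10 adjusted over the list alone), with Tap1 4.99-fold and Nlrc5 5.11-fold higher. Interferon-gamma response genes rose in 18 of 23 (18 adjusted over the list alone), with Serpina3g 14.8-fold and Gbp5 7.44-fold higher. Conventional dendritic cell genes rose in 4 of 11 (7 adjusted over the list alone), with Irf8 4.36-fold and Wdfy4 4.1-fold higher. Dectin-1 pathway genes rose in 11 of 16 (11 adjusted over the list alone), with Pycard 4.4-fold, Cybb 5.13-fold and Clec7a 2.77-fold higher, and complement genes in 8 of 10 (9 adjusted over the list alone). For these 12 lists all 6 tumours lay above every untreated tumour (exact adjusted p = 0.00634), and camera with an estimated correlation gave adjusted p of 0.0379 to 0.0492. With values rescaled to equal totals none passed the exact test (adjusted p = 0.0555 to 0.374).

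Macrophage genes rose in 14 of 15 (15 adjusted over the list alone), with C1qc 4.17-fold and Ctss 4.37-fold higher. Monocyte genes rose in 5 of 10 (7 adjusted over the list alone), with Ccr2 3.01-fold higher. Classically activated macrophage genes rose in 5 of 13 (5 adjusted over the list alone), with Cxcl9 11.8-fold and Cd86 6.65-fold higher. Exact adjusted p for these 3 lists was 0.00634, 0.00634 and 0.0111, and camera adjusted p was 0.0562, 0.113 and 0.183 with an estimated correlation. CD40 and NF-kB genes rose in 5 of 19 (7 adjusted over the list alone), with Cd40 itself 3.36-fold (log2 1.75 ± 0.39, adjusted p = 0.00256) and Traf1 2.93-fold higher. Type I interferon genes rose in 9 of 24 (10 adjusted over the list alone), inflammatory fibroblast genes in 7 of 14 (7 adjusted over the list alone) and endothelial genes in 6 of 16 (8 adjusted over the list alone). Exact adjusted p was 0.0629, 0.038, 0.0197 and 0.071, and camera adjusted p was 0.29, 0.414, 0.278 and 0.414 with an estimated correlation. Neutrophil genes moved both ways. Ngp (log2 5.26 ± 1.16), S100a8 (2.18 ± 0.51), S100a9 and Ly6g (at least 42.0-fold as a ratio of means, without reads in anti-CD40 tumour 6) rose. Ltf, lactoferrin, which epithelium also secretes (-1.53 ± 0.47), and Cxcr2 fell among 13 tested (5 rose and 2 fell adjusted over the list alone; exact adjusted p = 0.108, camera adjusted p = 0.48 with an estimated correlation). Collagen matrix genes did not pass as a list (camera adjusted p = 0.23): Dcn, Lum, Col5a1 and Col6a1 rose and Tnc fell among 23 (5 and 1 adjusted over the list alone). Cd274 (log2 0.36, adjusted p = 0.629), Tnf (0.81, 0.206) and Col1a1 (0.60, 0.132) did not pass.

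Epithelial genes fell in 11 of 19 (12 adjusted over the list alone) with anti-CD40, among them Elf3 (log2 -2.21 ± 0.42), Cdh1, which encodes E-cadherin (-1.75 ± 0.34), and the ductal keratin Krt19 (-1.88 ± 0.51, adjusted p = 0.013). All 6 tumours lay below every untreated tumour (exact adjusted p = 0.0111, camera adjusted p = 0.167 with an estimated correlation). Glycolysis and hypoxia genes fell in 12 of 20 (17 adjusted over the list alone), with Bnip3 at -1.18 ± 0.21 and Pfkl at -1.42 ± 0.27, and 5 of 6 tumours lay below every untreated tumour (exact adjusted p = 0.0157, camera adjusted p = 0.0492 with an estimated correlation). The largest falls were the proton channels Otop3 (log2 -6.22 ± 1.04) and Otop2 (-4.77 ± 0.87), Prap1 (-5.40 ± 1.17), Cym (-5.34 ± 0.9999), Mucl3 (-5.12 ± 1.18), the mucosal stress sensor Ern2 (-4.93 ± 0.84), Tmem212 (-4.86 ± 0.90) and the alcohol dehydrogenase Adh7 (-4.74 ± 1.14). Of all 14278 genes 9.10% had no overlap between the groups (chance share 0.433%), and 14 of the 59 named genes that passed lost their call in at least 1 alternative fit. The 2650 genes became 1651 with the acinar level as a covariate and 1699 with only these 2 groups fitted. Of those called with equal totals 22.2% were higher, against 59.3% of the 2650, where the median of all genes shifted by -0.576. Those totals include the acinar reads. They were 1.35e+07, 1.20e+07 and 3.81e+07 normalized counts in anti-CD40 tumours 2, 3 and 6, against 7.34e+06 to 1.13e+07 in untreated tumours. In anti-CD40 tumours 1, 4 and 5 they were 7.28e+06, 1.08e+07 and 8.53e+06. Rescaling thus lowers all genes most where the total is largest, and how far that accounts for the lost calls was not tested. With equal totals none of the 21 lists that passed the exact test did so (lowest adjusted p 0.0555). The T cell list stood at log2 2.33 ± 0.62 against 2.87, class II at 1.95 ± 0.53 against 2.52, macrophages at 0.99 ± 0.49 against 1.57, the Dectin-1 list at 0.74 ± 0.48 against 1.31 and epithelium at -1.83 ± 0.54 against -1.28. The type I interferon list also did not pass with the acinar level in a linear model or with quantile normalization (adjusted p = 0.114 and 0.0777).

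The combination raised myeloid, lymphoid and stromal transcripts and lowered epithelial ones. Krt19 fell by 4.31 ± 0.54 on the log2 scale (adjusted p = 3.46e-06), from a normalized count of 5199 ± 1356 (n = 5) to 292 ± 188 (n = 5). Mzb1 rose 184-fold (log2 7.52 ± 0.87), Jchain 162-fold, Ccl5 41-fold and the neutrophil granule genes Ngp and Camp 164-fold and 80.0-fold. Ly6g was at least 169-fold higher. The other leading rises were Ly6i (log2 6.88 ± 0.57), Ly6c2 (6.67 ± 0.48) and Cela2a. In all, 4849 genes changed, 2600 higher and 2249 lower, among them 3475 by at least 2-fold.

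Of T cell genes 17 of 18 (17 adjusted over the list alone) rose, with Cd3e 16.9-fold, Cd2 24.4-fold and Lck 10.3-fold higher. Of cytotoxic lymphocyte genes 12 of 14 (12 adjusted over the list alone) rose, with Nkg7 10.4-fold, Ifng 14.3-fold and Cd8a 5.15-fold higher. Of B cell genes 14 of 14 (14 adjusted over the list alone) rose, with Pou2af1 48.4-fold and Cd79b 37.1-fold higher. Plasma cell genes rose in 6 of 8 (7 adjusted over the list alone), with Sdc1 lower. Regulatory and inhibitory receptors rose in 9 of 10 (9 adjusted over the list alone), with the transcription factor Ikzf2 lower, and lymphoid tissue genes in 7 of 9 (7 adjusted over the list alone). Macrophage genes rose in 15 of 15 (15 adjusted over the list alone), with Ctss 7.4-fold and Adgre1, which encodes F4/80, 6.32-fold higher. Neutrophil genes rose in 11 of 13 (12 adjusted over the list alone), with S100a8 18.5-fold higher. Monocyte genes rose in 7 of 10 (7 adjusted over the list alone), with Ccr2 7.06-fold higher, and conventional dendritic cell genes in 6 of 11 (9 adjusted over the list alone). Classically activated macrophage genes rose in 10 of 13 (10 adjusted over the list alone), with Tnf 5.17-fold higher and the cytokine gene Il23a lower. Class II genes rose in 9 of 9 (9 adjusted over the list alone), with H2-Aa 6.49-fold and H2-Ab1 6.13-fold higher, and class I presentation genes rose in 11 of 13 (12 adjusted over the list alone). Interferon-gamma response genes rose in 18 of 23 (19 adjusted over the list alone), with Serpina3g 17.8-fold and Gbp5 9.11-fold higher, and type I interferon genes in 15 of 24 (17 adjusted over the list alone). Dectin-1 pathway genes rose in 14 of 16 (14 adjusted over the list alone), with Pycard 8.22-fold, Cybb 10.9-fold and Clec7a 5.57-fold higher. CD40 and NF-kB genes rose in 8 of 19 (8 adjusted over the list alone), with Cd40 5.46-fold higher. Cd274 rose 3.26-fold (log2 1.71 ± 0.46, adjusted p = 0.00594).

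Stromal lists rose as well. Collagen matrix genes rose in 14 of 23 (15 adjusted over the list alone), with Col1a1 3.43-fold, Col3a1 4.37-fold and the proteoglycan Dcn 7.66-fold higher. Inflammatory fibroblast genes rose in 9 of 14 (10 adjusted over the list alone), with Saa3 31.5-fold and Cxcl12 13.6-fold higher. Endothelial genes rose in 11 of 16 (12 adjusted over the list alone), with Pecam1 3.99-fold higher. Complement genes rose in 9 of 10 (9 adjusted over the list alone), with C1ra 8.63-fold and Serping1 6.57-fold higher. Matrix protease genes rose in 8 of 15 (8 adjusted over the list alone), with Mmp2 5.57-fold and Mmp9 6.31-fold higher. Cell death genes rose in 8 of 18 (8 adjusted over the list alone), with Tnfsf10, which encodes TRAIL, 12.2-fold and the inflammatory caspase gene Casp1 6.69-fold higher. The apoptotic caspase gene Casp8 was lower. For each of these immune and stromal lists all 5 tumours lay above every untreated tumour (exact adjusted p = 0.0125). With equal totals 6 of them no longer passed that test. These were collagen matrix (log2 0.75 ± 0.29 against 1.20, adjusted p = 0.0603), matrix protease (0.89 ± 0.36 against 1.35, 0.0697), CD40 and NF-kB (0.64 ± 0.27 against 1.09, 0.0603), cell death (0.27 ± 0.25 against 0.72, 0.371), type I interferon (0.60 ± 0.31 against 1.05, 0.141) and classically activated macrophage genes (1.57 ± 0.52 against 1.96, 0.0603). The endothelial list passed at 0.85 ± 0.25 against 1.31. On the authors' scaling the collagen matrix, matrix protease, CD40 and NF-kB, cell death and type I interferon lists rose by 0.72 to 1.35, near or below the endothelial 1.31. For these lists and the endothelial list a rise cannot be told apart from a lower share of epithelium, as this was not tested. Camera gave adjusted p from 1.37e-11 to 0.0327. With an estimated correlation the adjusted p was 0.0737 to 0.345, at which none of the 29 lists that passed held. The mast cell, eosinophil, migratory dendritic cell, adipocyte, smooth muscle, erythroid, hepatocyte, Schwann cell, suppressive macrophage and immediate early lists did not pass camera, at adjusted p from 0.0627 to 0.917. The NK cell and skeletal muscle lists had 3 tested members each and were not tested as lists; the NK cell genes Klrg1 and Klrd1 rose.

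Epithelial genes fell in 15 of 19 (15 adjusted over the list alone) with the combination, among them Cdh1 (log2 -3.03 ± 0.36), Onecut2, a transcription factor of ductal and endocrine lineage (-4.48 ± 0.54), and Elf3 (-3.48 ± 0.44), while Spint1, a protease inhibitor, was higher. Replication and mitosis genes fell in 10 of 23 (11 adjusted over the list alone), with the replicative helicase genes Mcm7 (-1.23 ± 0.21), Mcm3 (-1.34 ± 0.26) and Mcm6 (-1.15 ± 0.24) lower. Glycolysis and hypoxia genes fell in 10 of 20 (11 adjusted over the list alone), with Ndrg1 (-1.34 ± 0.29) and Ldha (-0.92 ± 0.22) lower. In each of these 3 lists all 5 tumours lay below every untreated tumour (exact adjusted p = 0.0125), and camera with an estimated correlation gave adjusted p = 0.0881, 0.314 and 0.18. With the acinar level in a linear model the replication and mitosis list did not pass (log2 -0.63 ± 0.31 against -0.77, adjusted p = 0.0802) and the glycolysis list was smaller (-0.65 ± 0.27 against -1.01, adjusted p = 0.0405). With equal totals the former was at -1.22 ± 0.39 and passed. The mesenchymal or basal-like and mesothelial lists, which both hold Krt14, moved both ways and did not pass camera (adjusted p = 0.608 and 0.922). Of the first 3 of 13 were higher and 5 lower (3 and 5 adjusted over the list alone), and of the second 2 of 4 were higher and 2 lower (2 and 2 adjusted over the list alone). Their mean levels were lower (log2 -0.94 and -1.09, exact adjusted p = 0.0241 and 0.0449), but with the acinar level in a linear model they did not pass (-0.56 ± 0.43 and -1.15 ± 0.54, adjusted p = 0.246 and 0.0729). Ribosomal protein genes passed camera downward with Rpl7, Rps12, Rpl3 and Rpl13 called of 20 (4 adjusted over the list alone; mean log2 -0.36, exact adjusted p = 0.13, camera adjusted p = 0.31 with an estimated correlation). The largest falls were Otop3 (log2 -8.73 ± 1.09), Prap1 (-8.47 ± 1.22), Adh7 (-8.31 ± 1.19), Cym (-7.82 ± 1.04), the tight junction gene Cldn18 (-7.59 ± 1.04), Mucl3 (-7.52 ± 1.23), the chymase gene Mcpt2 (-7.21 ± 0.79) and Fam83e (-7.20 ± 1.12). Of all 14278 genes 21.9% had no overlap between the groups (chance share 0.794%), and 5 of the 62 named genes, all of which passed, lost their call in at least 1 alternative fit. With equal totals 33.3% of calls were higher, against 53.6%, as the median of all genes shifted by -0.451; in that fit the cell death list no longer passed camera.

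**Figure D2:**
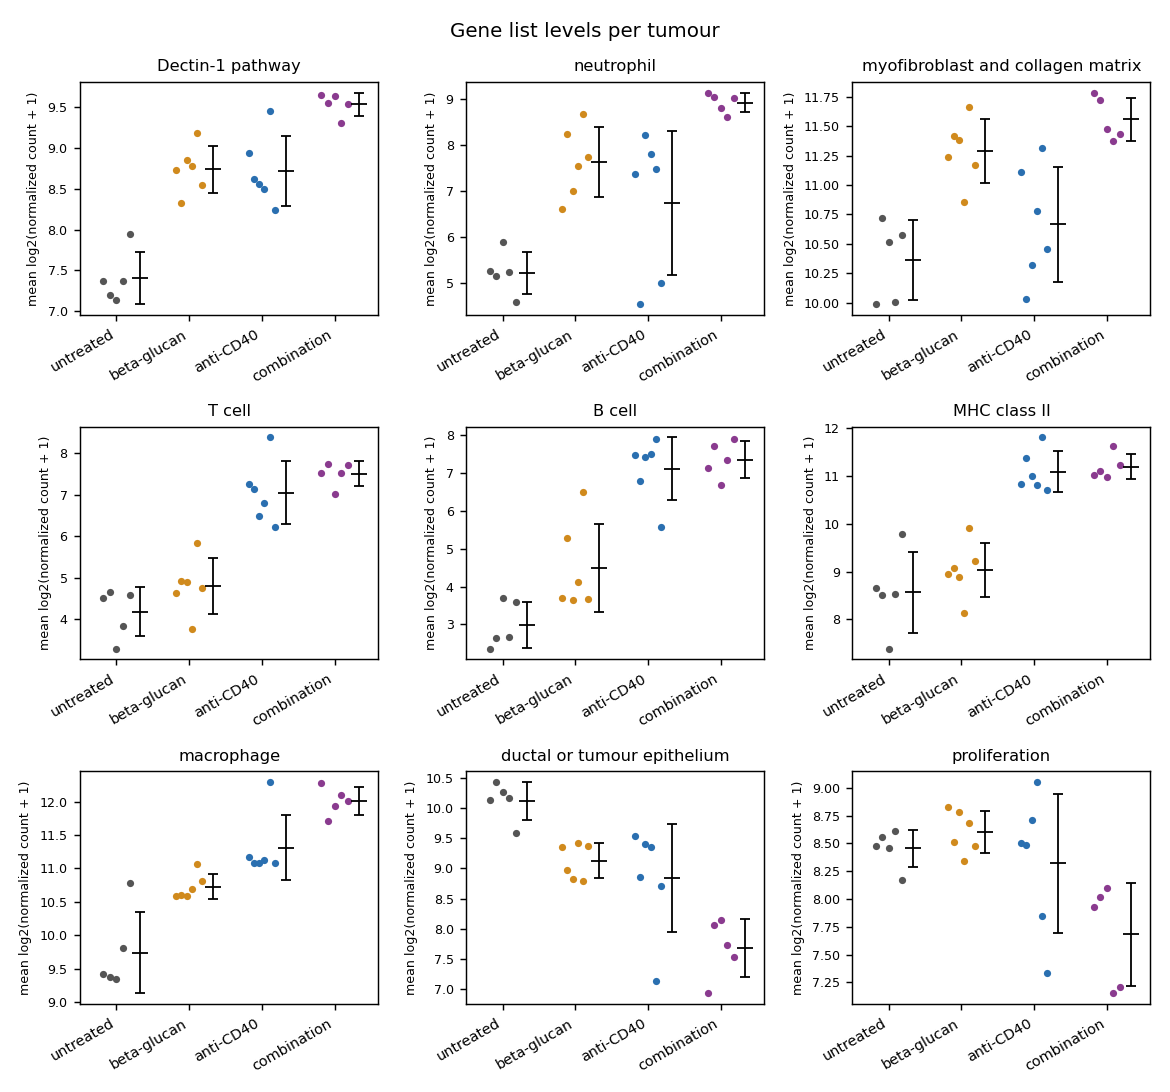
Mean log2(normalized count + 1) over the genes of 9 lists (vertical axes) in the 4 groups; points are tumours and bars the mean ± SD. The T cell list lies higher in all 6 anti-CD40 and all 5 combination tumours than in every untreated tumour, and the epithelium list lies lower in all treated tumours.

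**Figure D3:**
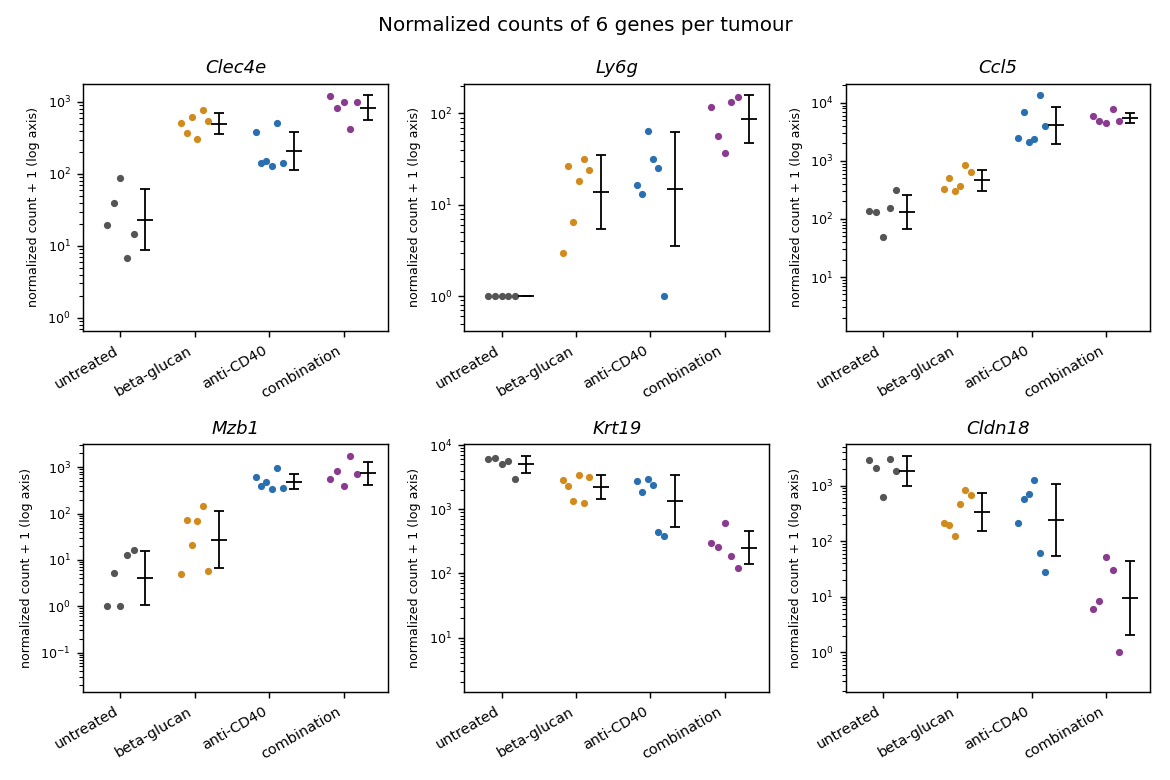
Normalized counts + 1 (log axis) of Clec4e, Ly6g, Ccl5, Mzb1, Krt19 and Cldn18 in the 4 groups; points are tumours and bars the mean ± SD on the log2 scale. Clec4e rises from 32.5 in untreated to 517 in beta-glucan tumours, and Krt19 falls from 5199 in untreated to 292 in combination tumours.

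Positions in mm10 were taken from RefSeq for the genes plotted and a few others, all protein coding. Clec7a lies on chromosome 6 at 129461591 to 129472785 and Clec4e on the same chromosome at 123281789 to 123289871. Cd40 lies on chromosome 2 at 165055614 to 165071654, Mzb1 on chromosome 18 at 35647265 to 35650266 and Cldn18 on chromosome 9 at 99690796 to 99717267. On chromosome 11 lie Krt19 (100140810 to 100145926), Col1a1 (94936224 to 94953042) and Ccl5 (83525778 to 83530518). On chromosome 15 lie Dcstamp (39745930 to 39760938), Ly6g (75155261 to 75159128), Glycam1 (103562759 to 103565081) and Tuba1a (98949847 to 98953501).

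Against beta-glucan alone, combination tumours held more lymphocyte and class II transcripts and fewer epithelial and replication transcripts. Depth was 7.13 to 8.74 M reads with beta-glucan and 12.2 to 18.8 M with the combination. These ranges did not overlap, so an effect of depth, or of anything that went with it, cannot be told apart from the treatment. Mzb1 was higher by log2 4.75 ± 0.83 and Jchain by 4.60 ± 0.63 (n = 5 and 6). The granzyme genes Gzmf and Gzmg were higher by 4.35 ± 1.06 and 4.29 ± 0.99. Cxcr3, a chemokine receptor of effector T cells, was higher by 4.20 ± 0.71 and Ubash3a, a regulator of T cell receptor signalling, by 4.22 ± 0.86. The other leading rises were Obp2b (4.63 ± 1.12) and Slpi (4.26 ± 0.54). In all, 2013 genes differed, 926 higher and 1087 lower. T cell genes rose in 15 of 18 (16 adjusted over the list alone), with Cd6 11.4-fold and Lck 7.25-fold higher, and cytotoxic lymphocyte genes in 10 of 14 (11 adjusted over the list alone), with Ccl5 11.8-fold and Nkg7 7.2-fold higher. B cell genes rose in 12 of 14 (13 adjusted over the list alone), with Pou2af1 11.4-fold and Cd22 5.14-fold higher. Class II genes rose in 9 of 9 (9 adjusted over the list alone), with H2-Eb1 4.83-fold and H2-Ab1 4.41-fold higher. Macrophage genes rose in 14 of 15 (15 adjusted over the list alone), with Adgre1 3.01-fold and C1qc 2.43-fold higher. Type I interferon genes rose in 13 of 24 (16 adjusted over the list alone), with Irf7 2.68-fold and Ifih1 1.94-fold higher, and conventional dendritic cell genes in 4 of 11 (7 adjusted over the list alone), with Irf8 2.68-fold higher. Exact adjusted p for these 7 lists lay between 0.0127 and 0.0157, with 4 or 5 of 5 tumours above every beta-glucan tumour. Camera gave adjusted p from 2.36e-14 to 2.03e-05, and adjusted p from 0.0611 to 0.2 with an estimated correlation. Camera also passed the plasma cell list (5 of 8, 5 adjusted over the list alone, with Sdc1 lower), the regulatory and inhibitory receptors (5 of 10, 7 adjusted over the list alone), interferon-gamma genes (15 of 23, 16 adjusted over the list alone), and class I presentation (8 of 13, 10 adjusted over the list alone). It further passed complement (6 of 10, 8 adjusted over the list alone), the Dectin-1 pathway (7 of 16, 9 adjusted over the list alone), monocyte genes (4 of 10, 4 adjusted over the list alone, with Vcan lower), lymphoid tissue genes (4 of 9, 6 adjusted over the list alone), endothelial genes (4 of 16, 8 adjusted over the list alone) and acinar genes (1 of 22, 1 adjusted over the list alone). Their adjusted p was 0.0771 to 0.579 with an estimated correlation. The exact adjusted p was 0.0137 to 0.0187, apart from 0.0579 for class I presentation and 0.127 for acinar genes. Ly6g, S100a8 and Ngp rose among 13 neutrophil genes (3 adjusted over the list alone; exact adjusted p = 0.0222, camera adjusted p = 0.454 with an estimated correlation). The collagen list did not pass (camera adjusted p = 0.126; Dcn and Lum called of 23, 1 adjusted over the list alone).

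Epithelial genes were lower in 9 of 19 (12 adjusted over the list alone) than with beta-glucan alone, among them Onecut2 (log2 -3.43 ± 0.51) and Krt19 (-3.14 ± 0.51). Proliferation genes were lower in 13 of 23 (15 adjusted over the list alone), with Mcm7 (-1.10 ± 0.20) and the cyclin gene Ccnb1 (-1.37 ± 0.29). Mesenchymal or basal-like genes were lower in 3 of 13 (5 adjusted over the list alone), among them Krt14 and Cdh2. In the 3 lists all 5 tumours lay below every beta-glucan tumour (exact adjusted p = 0.0127), and camera with an estimated correlation gave adjusted p = 0.145, 0.161 and 0.304. The largest falls were Adh7 (log2 -6.42 ± 1.14), Mcpt2 (-6.22 ± 0.76), Otop3 (-6.15 ± 1.04), Lgals2 (-6.14 ± 0.84), Phlda2 (-5.93 ± 1.13), Prap1 (-5.84 ± 1.17), Vsig1 (-5.80 ± 1.05) and Chst4 (-5.79 ± 0.72). Of all 14278 genes 11.5% had no overlap between the groups (chance share 0.433%), and 6 of the 33 named genes lost their call in at least 1 alternative fit. The 2013 genes became 1206 with equal totals, 11.2% of them higher against 46.0% (median shift -0.499), and 1008 without the tumours with over 30% acinar reads. With equal totals the monocyte, neutrophil, interferon-gamma, type I interferon, lymphoid tissue, Dectin-1, endothelial and complement lists no longer passed the exact test (adjusted p = 0.104 to 0.624), at differences of log2 0.15 to 0.95 against 0.65 to 1.37. In that scaling macrophages stood at 0.78 ± 0.22 against 1.28, conventional dendritic cells at 0.80 ± 0.21 against 1.29 and proliferation at -1.42 ± 0.35 against -0.92. With the acinar level in a linear model the endothelial list did not pass (adjusted p = 0.0533).

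Against anti-CD40 alone, 212 genes differed in combination tumours, 94 higher and 118 lower, with 2237 at an unadjusted p under 0.05. No list passed the exact permutation test after adjustment or camera with an estimated correlation (lowest adjusted p 0.0666 and 0.101). Serpinb2, an inhibitor of plasminogen activators, was higher by log2 5.40 ± 0.73 (adjusted p = 0.00151, n = 5 and 6), Sprr2e, a small proline-rich protein of squamous epithelium, by 5.49 ± 0.84 (0.00456), and Il1f9, a cytokine of the interleukin-1 family, by 4.70 ± 0.92. Cxcr2, the main chemokine receptor of neutrophils, and its ligand Cxcl2 were higher by 3.58 ± 0.63 and 3.56 ± 0.57. The other leading rises were Slc6a12 (3.45 ± 0.88), Mirt2 (3.35 ± 0.66) and Car4 (3.16 ± 0.72). Cxcr2, Il1r2 (log2 1.64 ± 0.37) and S100a8 (2.03 ± 0.51) rose among 13 neutrophil genes (10 adjusted over the list alone). Of collagen matrix genes 6 of 23 (15 adjusted over the list alone) rose, with Col3a1 at 1.45 ± 0.27 and Thbs2 at 1.40 ± 0.28. The matrix protease genes Mmp9 (1.58 ± 0.37), Mmp13 (2.01 ± 0.48) and Mmp3 (2.56 ± 0.64) rose among 15 (10 adjusted over the list alone). The complement genes C3ar1 (1.19 ± 0.27) and Serping1 (1.14 ± 0.28) rose among 10 (7 adjusted over the list alone). Ncf1 (1.16 ± 0.28) rose among 16 Dectin-1 pathway genes (12 adjusted over the list alone) and Itgam (1.62 ± 0.36) among 10 monocyte genes (3 adjusted over the list alone). Cd68 rose among 15 macrophage genes (7 adjusted over the list alone) and Saa3 (3.06 ± 0.55) among 14 inflammatory fibroblast genes (3 adjusted over the list alone). No endothelial gene of 16 was called (3 adjusted over the list alone; camera adjusted p = 3.37e-05, adjusted p = 0.416 with an estimated correlation, exact adjusted p = 0.283).

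Tspan8 (log2 -3.02 ± 0.61), Krt19 (-2.43 ± 0.51), Onecut2 and Krt18 were lower than with anti-CD40 alone among 19 epithelial genes (9 adjusted over the list alone). Ccnb1 (-1.24 ± 0.29) and Mcm7 (-0.79 ± 0.20) were lower among 23 proliferation genes (9 adjusted over the list alone). The largest falls were Lgals2 (-5.48 ± 0.84), Mcpt2 (-4.68 ± 0.76), Cldn18 (-4.66 ± 0.9954), Vsig1 (-4.22 ± 1.05), Glod5 (-4.17 ± 0.93), Adam28 (-3.76 ± 0.83), Pax9 (-3.44 ± 0.80) and Plut (-3.40 ± 0.69). Camera passed 12 lists at adjusted p from 7.61e-12 to 0.00812, and none with an estimated correlation (adjusted p from 0.101 to 0.468). The smallest exact adjusted p, 0.0666, was that of the neutrophil, collagen, Dectin-1 and complement lists, with 4 or 5 of 5 tumours above every anti-CD40 tumour. T cell, cytotoxic lymphocyte, B cell, class II and interferon-gamma genes had 0 calls each (0 adjusted over each list alone; camera adjusted p = 0.0749 to 0.857). Ribosomal protein genes had 0 calls of 20 (0 adjusted over the list alone; exact adjusted p = 0.127).

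The comparison with anti-CD40 alone rested on few tumours. The 212 genes became 28 without anti-CD40 tumour 2, 33 without anti-CD40 tumour 3, 41 without anti-CD40 tumour 4, 119 without anti-CD40 tumour 1, 854 without anti-CD40 tumour 5 and 396 without anti-CD40 tumour 6. They became 45 without combination tumour 1, 82 without combination tumour 2, 82 without combination tumour 4 and 60 without combination tumour 5, and 123 without untreated tumour 1, 124 without beta-glucan tumour 1 and 117 without beta-glucan tumour 2. They became 8 with equal totals (62.5% higher against 44.3%), 3 without the tumours with over 30% acinar reads, 6 with only these 2 groups fitted, and 665 with DESeq2 on recovered reads, 33.1% of them higher. EdgeR called 148, 29.7% of them higher. All 32 named genes lost their call in at least 1 alternative fit, and 1.27% of all 14278 genes had no overlap between the groups (chance share 0.433%).

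For 3 genes the combination fell short of the sum of the single effects on the log2 scale. The interaction was -2.92 ± 0.50 for Dcstamp (adjusted p = 0.0385), with normalized counts of 10.9 ± 3.26 in untreated, 245 ± 47.4 in beta-glucan, 66.5 ± 30.9 in anti-CD40 and 179 ± 83.8 in combination tumours (n = 5, 6, 6 and 5). It was -1.74 ± 0.31 for Tuba1a, an alpha-tubulin (adjusted p = 0.0486), with 1592 ± 379.6, 3595 ± 224, 3024 ± 833 and 2126 ± 683. Glycam1 (-4.60 ± 0.75, adjusted p = 0.0318) had no reads in untreated tumours, and its value depends on the pseudocount, with means of 16.5, 69.8 and 45.4 in the treated groups. No gene lay above the sum; 1194 genes had an unadjusted p under 0.05. None of the 10 readouts passed (lowest adjusted p 0.451). Clec7a stood at log2 -1.06 ± 0.42, Cd40 at 0.01 ± 0.55, Cd274 at 0.39 ± 0.63, Ifng at -0.05 ± 1.0010 and Tnf at -0.06 ± 0.61. Ccr2 stood at -0.05 ± 0.61, Cd3e at -1.02 ± 0.78, Cd8a at -0.59 ± 0.58, Krt19 at -1.26 ± 0.73 and Col1a1 at -0.13 ± 0.38.

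Camera passed 10 lists for the interaction, 9 of them negative. Of 23 interferon-gamma genes 0 were called (15 below 0 adjusted over the list alone; mean -1.11), with Serpina3g at -2.08 ± 0.52 and Gbp2 at -2.08 ± 0.55. B cell genes averaged -1.25 (0 of 14 called, 2 adjusted over the list alone), with Cd79b at -2.38 ± 0.73 and Pou2af1 at -1.82 ± 0.56. Proliferation genes averaged -0.79 (0 of 23 called, 3 adjusted over the list alone), with Ccnb1 at -1.62 ± 0.41 and Foxm1 at -1.59 ± 0.42. Lymphoid tissue genes averaged -1.65 (Glycam1 called of 9, 4 adjusted over the list alone) and class I presentation genes -0.85 (0 of 13, 2 adjusted over the list alone). Classically activated macrophage genes averaged -0.90 (0 of 13, 3 adjusted over the list alone) and Dectin-1 genes -0.51 (0 of 16, 0 adjusted over the list alone). Acinar genes averaged -2.23 (0 of 22, 0 adjusted over the list alone) and islet genes -2.86 (0 of 14, 0 adjusted over the list alone). Glycolysis and hypoxia genes averaged 0.96 (0 of 20, 4 above 0 adjusted over the list alone), with Bnip3 at 1.32 ± 0.29 and Pgam1 at 2.40 ± 0.70. Camera adjusted p lay between 3.49e-09 and 0.0344, and adjusted p between 0.216 and 0.791 with an estimated correlation, so none held. In simulated data limma recovered 68% of genes with a 4-fold interaction above 0, 52% of those with one of 0.25, and 8% of those with one of 2 or of 0.5. The 3 genes became 0 without untreated tumour 1, 2 or 5, without beta-glucan tumour 1, 2, 3 or 5, without anti-CD40 tumour 1 or 2, and without combination tumour 4 or 5. They became 1 without anti-CD40 tumour 3, 6 without anti-CD40 tumour 6, 8 without anti-CD40 tumour 5 and 12 without untreated tumour 6. They became 0 at a pseudocount of 8, with either other scaling and without the tumours with over 30% acinar reads, against 98 with DESeq2. Camera passed 19 lists without untreated tumour 6 and 18 without the tumours with over 30% acinar reads.

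The changes against untreated overlapped between treatments. Of genes called with beta-glucan and with anti-CD40, 571 were higher and 153 lower in both and 1 went opposite ways. Independent lists would share 80.0 and 14.3. Beta-glucan and the combination shared 694 higher and 169 lower genes (132 and 29.8 for independent lists), and anti-CD40 and the combination 1471 and 906 (286 and 170), with 0 and 3 in opposite directions. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.748, 0.763 and 0.876 for these 3 pairs. In 100 simulations of unchanged groups, residuals of all tumours were dealt at random into the groups. The contrasts of a pair thus shared their simulated controls, but these were not the untreated tumours themselves. Simulated r had means of 0.553, 0.530 and 0.532 and highest values of 0.784, 0.797 and 0.800. The first 2 observed values lay within the simulated range. What r the spread of the untreated tumours alone would give was not tested. The covariances were 0.636, 0.840 and 1.38, against simulated values of 0.169, 0.172 and 0.172. With the untreated tumours split between the contrasts, r was 0.4664, 0.527 and 0.698 over 20 splits and the shared calls 235, 353 and 1110 in place of 724, 863 and 2377.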

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

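The omission of the anti-CD40 tumour with the most acinar reads, the exact permutation tests of the acinar level and the rearrangement of residuals were tests chosen after the result was seen; the other tests in this part were stated before their results were seen. Of 216 group values examined, 18 had a tumour far from the rest of its group, where 10.8 would be expected by chance at 1 in 20.

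Acinar reads made up 17.3% of untreated tumour 6, against 0.0383 to 3.75% in the other untreated tumours, and the acinar list was lowest in combination tumour 1 (mean log2 level 9.69, others 14.5 to 16.2). The difference between anti-CD40 and untreated tumours did not come from the most acinar tumour alone: without anti-CD40 tumour 6 it was 4.32 on the log2 scale against 5.11 with it, though neither passed the exact permutation test (p = 0.135 and 0.0671, two-sided). Normal pancreas inside the sections may account for it, since within groups the acinar level followed the islet level over 22 tumours (r = 0.646, rho = 0.762, permutation p = 0.00511, Benjamini-Hochberg 0.0204 over 4 relations, r = 0.676 without the 2 tumours farthest from the median). Whether acinar tissue took the place of tumour epithelium cannot be told apart from no relation, as the acinar level did not track the epithelium level within groups (r = -0.0101, rho = -0.281, permutation p = 0.970, adjusted 0.970, r = 0.205 without the 2 farthest). How the sections were placed, or an effect of anti-CD40 on the margin of the tumour, was not tested and remains open.

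The interaction passed for Glycam1 (log2 -4.60), Dcstamp (-2.92) and Tuba1a (-1.74), and by camera at the preset correlation for the lists of B cell (-1.25), classically activated macrophage (-0.90), class I presentation (-0.85), interferon-gamma (-1.11), lymphoid tissue (-1.65), Dectin-1 (-0.51), acinar (-2.23), islet (-2.86) and proliferation (-0.79) genes and, above 0, glycolysis and hypoxia (0.96). The log2 scale may produce the negative list values, since effects that add up in reads fall short of their sum in logs. On a linear scale 1 of the 9 negative lists, proliferation (-0.469, standard error 0.190), lay more than 2 standard errors below 0. For the other 8 lists no departure from addition of reads was shown, and for proliferation an interplay of the treatments stays open. The linear rule rests on the spread of list levels between tumours, and camera at the preset correlation does not. Scale and test thus changed together, so the lower count cannot be assigned to the log2 scale. In 100 arrangements of the tumours' residuals from an additive fit, the real one included, chance cannot be excluded for the count of 10 lists (highest other 27, 41 as large). The count of 3 genes met the threshold of 5 in 100 (3 as large, the real one included). That test was chosen after the result was seen and was not adjusted for the other counts tested in this way. The highest other arrangement called 1348 genes, which points to structure among the tumours, and no gene passed in 11 of the fits with 1 tumour left out. Chance is thus not excluded for the 3 genes either.

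Other tumours far from their group are given as values. Combination tumour 2 had 18.8 M reads (others 12.2 to 13.3 M), and combination tumour 4 had 4.79% of its reads in Rn45s (others 1.84 to 2.44%). Anti-CD40 tumour 5 had the highest level of regulatory and inhibitory receptors (7.73, others 6.08 to 6.47) and of macrophage genes (12.3, others 11.1 to 11.2) and the lowest of epithelium (7.14, others 8.71 to 9.54). Anti-CD40 tumour 2 was lowest for suppressive macrophage (6.22, others 7.20 to 7.74) and eosinophil genes (1.35, others 3.31 to 4.44), and anti-CD40 tumour 6 for cell death genes (7.62, others 8.24 to 8.61). Combination tumour 4 was lowest for classically activated macrophage genes (5.58, others 7.26 to 7.83), immediate early genes (6.88, others 8.09 to 8.53) and the normalized count of Cd274 (163, others 524 to 590). Combination tumour 3 was highest for eosinophil genes (4.18, others 3.15 to 3.30) and combination tumour 1 for complement genes (11.01, others 10.7 to 10.8). Beta-glucan tumour 5 was highest for conventional dendritic cell genes (5.93, others 4.97 to 5.20) and beta-glucan tumour 6 for the normalized count of Ifng (17.2, others 1.06 to 5.96). Untreated tumour 6 was lowest for ribosomal protein genes (11.5, others 12.2 to 12.4).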

How the results depend on the processing

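The acinar covariate, the omission of tumours with over 30% acinar reads and the exact test of list levels were chosen after the results were seen. Of 261 named gene results, 233 passed; 153 of these kept direction and call in every setting that applied to them, 80 lost the call in at least 1 and 0 reversed. Over 9347 pairs of gene and setting 8650 kept direction and call, 612 lost and 27 gained it, and 58 reversed; the cause was not tested where none is given.

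Genes changed by beta-glucan (916) were 257 with equal totals, 2630 with sample weights (64.2% higher) and 506 to 1098 with 1 tumour left out (61.2% higher with only the 2 groups). Anti-CD40 (2650) gave 1699 with only 2 groups, 1651 with the acinar covariate and 2054 to 2852 with 1 tumour left out, and the combination (4849) 4121 to 5229. Against beta-glucan (2013) it gave 1206 with equal totals, 3543 with weights, 1008 without tumours over 30% acinar, which leaves fewer tumours, and 1401 to 2432. Against anti-CD40 (212) it gave 8 with equal totals, 665 with DESeq2, 744 with weights, 6 with only 2 groups (66.7% higher), 3 without the acinar tumours (33.3% higher) and 28 to 854. The interaction (3) gave 0 at a pseudocount of 8, with equal totals, with quantile normalization and without the acinar tumours, 98 with DESeq2, 49 with weights and 0 to 12. Equal totals shifted the median of all genes by 0.127 for the combination against anti-CD40, and quantile normalization by -0.0988 for the combination against untreated, its largest shift.

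With an estimated correlation 0, 13, 0, 0, 0 and 0 lists passed in the 6 contrasts; against anti-CD40 7 passed by fry and 19 at a pseudocount of 8, and for the interaction 1 by fry and 18 without the acinar tumours. With 1 tumour left out the lists were 23 to 27, 23 to 25, 27 to 30, 20 to 24, 11 to 18 and 9 to 19. No list that passed camera reversed under either scaling. By the exact test of levels 18, 21, 29, 22 and 0 lists passed in the 5 contrasts of 2 groups, 19, 0, 22, 15 and 0 with equal totals and 17, 20, 29, 23 and 0 with quantile normalization. With the acinar level in a linear model, which is another test, 21, 23, 26, 20 and 6 of 40 did. Against beta-glucan the CD40 and NF-kB level (0.43) reversed to -0.0581 with equal totals, and the Schwann cell and mesothelial lists, among others, lost their call. Shared calls with the untreated tumours split, so with fewer controls, were 235, 353 and 1110 against 724, 863 and 2377. Medians of lists with a group without reads moved only for plasma cells when bounded: 0.76 to 0.88, 3.10 to 3.86 and 4.23 to 4.47.

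Reversed values were all of genes that did not pass. Ifng with beta-glucan (0.17) was -0.00396 at a pseudocount of 8, -0.51 quantile, -0.00939 edgeR, -0.0156 DESeq2, -0.42 weights and -0.359 to 0.582 with 1 tumour left out; Cd274 with anti-CD40 was -0.21 with equal totals. In the interaction Cd40 (0.01) was -0.12 edgeR, -0.0925 DESeq2, -0.16 weights, -0.17 without the acinar tumours and -0.229 to 0.272 with 1 tumour left out. Ifng (-0.05) was 0.0926 at a pseudocount of 8, 0.0729 equal totals, 0.65 quantile, 0.94 weights and -0.465 to 0.476. Tnf (-0.06) was 0.00345 at a pseudocount of 8, 0.11 quantile, 0.41 weights and -0.39 to 0.27. Ccr2 (-0.05) was 0.0229 equal totals, 0.0381 quantile and -0.451 to 0.17, and Col1a1 (-0.13) -0.317 to 0.0562.

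The labels do not say whether replicate numbers pair the tumours. Over 30 pairs of tumours with 1 number the correlation of deviations was -0.271 to 0.338, and 8 were over 0.1. The median was 0.0283, against 0.00305 for pairs with different numbers. Little pairing was thus seen, but low correlations cannot exclude a shared origin. With the number as a block, genes against anti-CD40 were 330 by description number, the interaction 8 by title and 9 by description number, and Ifng and Tnf in the interaction 0.0344 and 0.0323 by description number; no other count moved by over 1.5 times. Of 22 tumours 5 by title and 4 by description number correlated best with their own number. Depth of 6.33 to 21.2 M reads limits the genes with few reads. In simulated data, where most genes were unchanged and the adjusted threshold was thus strict, 2-fold changes were mostly missed.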

Other observations

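The tests in this part of acinar content, scaling, epithelium share, the make-up of draws and the difference of the 2 correlations of Mcpt2 were chosen after the result was seen, as was the list of 8 gastric-type genes, set up because stomach genes stood among the largest falls; the other tests were stated before their results were seen.

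On average the tested genes of gastric-type epithelium fell further with the combination than the epithelium list. Of the 8 genes listed 5 were tested, and 4 were lower: Anxa10 (log2 -6.78), the aspartic protease Ctse (-5.00) and the gastrokines Gkn1 (-5.11) and Gkn2 (-3.45), while Gkn3 stood at -1.19 (adjusted p = 0.248). The mean change of the 5 was -4.31 against -2.43 for the epithelium list, a difference of -1.88 (exact permutation test, p = 0.0159, two-sided, n = 5 and 5). As the list was set up from falls of stomach genes in these same tumours, this p is not independent support. Mcpt2, a chymase of mucosal mast cells by its usual annotation, correlated with the epithelium list within groups over 22 tumours (r = 0.544, rho = 0.588, permutation p = 0.0211, Benjamini-Hochberg 0.0422 over 4 relations, r = 0.511 without the 2 tumours farthest from the median); with the mast cell list r was 0.0564 (adjusted p = 0.970). The difference of the 2 r, 0.488, had a 95% interval of -0.175 to 1.20 (10000 bootstrap resamples within groups), so whether Mcpt2 follows the epithelium rather than the mast cell genes stays open.

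The joint rise of immune lists and fall of the epithelium list with the combination could have a technical source. Acinar content does not account for it: with the acinar level in a linear model of list levels over 22 tumours, all 15 immune lists that passed upward, of 18, kept a higher level (highest adjusted p 0.0235; T cell list 3.61 ± 0.45 against 3.33 without), and the epithelium list stood at -2.42 ± 0.43 against -2.43. Nor does the scaling, since a factor per tumour moves all lists alike: 13 of the 15 kept a higher level under both other scalings (exact permutation test, adjusted p under 0.05), while the epithelium list stood at -2.86 for equal totals and -2.57 for quantile normalization (adjusted p = 0.0181 and 0.0121); for the other 2 scaling cannot be told apart from a rise: with equal totals, which lowered most genes, the type I interferon list went from 1.05 ± 0.28 to 0.60 ± 0.31 (adjusted p = 0.141) and the classically activated macrophage list from 1.96 ± 0.42 to 1.57 ± 0.52 (adjusted p = 0.0603). A lower share of epithelium that raises every other cell type alike would lift T cell and endothelial genes equally, but T cell genes rose further by 2.02 on the log2 scale (3.33 against 1.31; exact permutation test, p = 0.00794, the smallest that 252 splits can give, two-sided, n = 5 and 5). Other lists were not compared with the endothelial list. Depth was not tested as a source: it was 12.2 to 18.8 M reads with the combination and 7.38 to 9.34 M in untreated tumours. These ranges did not overlap, so an effect of depth, or of anything that went with it, cannot be told apart from the treatment. More immune cells, more transcripts per cell and a loss of epithelium all stay open, since bulk sections give no cell numbers.

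Groups of the same sizes were drawn 99 times from the compared tumours, and the real grouping made 100. The counts of groupings as large include the real one. Chance was excluded for the count of genes changed by beta-glucan (916, highest other draw 22, 1 as large), anti-CD40 (2650, 939, 1), the combination (4849, 2297, 1) and the combination against beta-glucan (2013, 896, 1). It was not excluded for the combination against anti-CD40 (212, highest other 605, 5 as large). Nor was it for the counts of lists that passed camera at the preset correlation: beta-glucan (24, highest other 31, 13 as large), anti-CD40 (24, 32, 15), the combination (29, 31, 7), against beta-glucan (21, 25, 16) and against anti-CD40 (12, 25, 34). The draws that called 605, 939 and 2297 genes had 9 of 11, 9 of 11 and 8 of 10 tumours sorted as in the real groups, or with the 2 groups exchanged, against medians of 7, 7 and 6 over the draws. The rank correlation of gene count and sorting over the draws was 0.237, 0.421 and 0.503. For the combination against untreated 20 of the 99 draws were sorted at least as well as the largest, while 91 called no gene. Some draws sorted as well thus called none, and sorting alone does not account for the large counts.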
